A study of Homo sapiens and Mus musculus with 7 samples.

How the data were processed

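RNA-seq and ChIP-seq data were analysed. RNA-seq was done in HEL cells, a human erythroleukaemia line, with KAP1 knocked down or not, and with or without hemin at 50 µM for 5 days. The table's control columns are headed Ctrl, while the labels say KAP1 WT. They were matched because KAP1 WT is the other genotype among the HEL samples listed, and every knockdown ratio rests on this match. Each of these 4 groups was 1 library, made from 250 ng of total RNA, so there was no replicate of any group. ChIP-seq was done in mouse bone marrow cells sorted for CD71 and Ter119, from animals of 8 to 12 weeks, with 1 KAP1 library, 1 IgG library and 1 library of total input chromatin.

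Expression values were deposited as RPKM per RefSeq transcript, per the file headers. Bowtie and the human build hg19 are named in the submitters' processing notes, with no version or role. Other steps are not given in the sources used here. The table held 24538 rows, 24408 distinct transcripts and 14946 gene symbols, and no value was 0. A transcript with no reads in at least 1 of the 4 libraries is thus absent, or something was added to its value. Which of these holds is not given in the sources used here. If such transcripts were left out, genes silent in 1 group are missing from every count of differences below. Within a row the 4 deposited RPKM values were whole multiples of a single step once each column was divided by a factor near 1. The values are therefore reads over transcript length times a factor per library, and they were not scaled to the reads on these transcripts. Whole reads came out for 24532 of the 24533 rows without whole numbers, within a tolerance of 0.0002 reads plus a relative precision of 4e-09. A set of reads that shares a common factor is recovered divided by it, which 7.61% of random sets of 4 whole numbers do, and its counting interval is then too wide.

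The remaining 5 rows held whole numbers in all 4 columns, unlike every other row: TRIM28, BNIP3L, BECN1, ATG12 and a transcript of BAD. How these rows were made is not given in the sources used here. The other BAD transcript gave a check. The whole-number row was 0.733 to 0.763 times its deposited values in the 4 libraries, with a coefficient of variation of 1.83%, and 1.51 to 1.69 times its reads, with one of 5.16%. The BAD row thus followed the deposited values more closely than the reads, and both still carry depth. Values and reads differ only by a factor near 1 per library, and counting noise was not set against these 2 spreads. The check therefore does not decide whether the row holds values or reads. The same could not be checked for the other 4 genes, so their ratios were scaled like those of all other genes and are given with this limit.

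The groups, the test design, the gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. That design assumed RPKM already scaled to depth. Since the values were not, they were first divided by the value of a single read and by the effective read total of each library. That total was the recovered reads on the chosen transcripts times a factor from the trimmed mean of log ratios, or TMM, with trims of 0.3 and 0.05. A single constant set the mean sum of a library to 1000000, and the resulting unit is called scaled TPM. Each gene was represented by its transcript with the highest mean value, which gave 14900 genes. Fold changes are on the scale of log2 of scaled TPM plus a pseudocount of 0.5, which understates the change of low genes. Genes entered a comparison when the higher of its libraries reached 5 scaled TPM, and a 2-fold difference was the limit for counting. Exact conditional binomial intervals at 95% were computed on the reads without a pseudocount, so for low genes the ratio can lie outside its interval. None was computed for the rows of whole numbers, whose reads are not known. The intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and say nothing of the spread between cultures.

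Reads on the chosen transcripts numbered 23294701 in the knockdown without hemin, 40777133 in the knockdown with hemin, 32903389 in the control without hemin and 36529794 in the control with hemin. TMM factors were 1.01, 1.03, 0.954 and 1.00 in the same order. The median width of a counting interval was between 0.21 and 0.25 on the log2 scale.

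With 1 library per group, comparisons of 2 libraries describe those libraries and carry no p-value. A secondary additive model with knockdown and hemin as terms was fitted with limma (version 3.58.1 in R 4.3.3) on log2 of scaled TPM plus 0.5, with a trend on expression and Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom, which is the interaction itself, and limma pooled the spread over all genes of like expression without limit. Its p-values rest on that pooling. There were 25 gene lists. Each list's median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins, when at least 5 members reached the floor. Members at least 1.5-fold apart were counted. Genes named in the text were TRIM28, the 12 highest and 12 lowest by the smaller of the 2 log2 ratios for each of knockdown and hemin, the 5 highest and 5 lowest differences of the knockdown effect, and up to 4 members of each list with the largest ratios. Other genes were named after their values were seen: BECN1 and BAD, with rows of whole numbers, RNAs without a poly-A tail, genes with opposite differences in the 2 states or genotypes, and genes of the adjacent pairs. The 10 peaks with the highest score were taken. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.

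KAP1 peaks were deposited as a list with a score per peak, whose names begin with MACS per the file itself. Bowtie and the mouse build mm9 are named in the submitters' processing notes. Which control was used, what was removed as repeats and how the score was made are not given in the sources used here. Peaks were described by number, width, score and chromosome, and no mouse annotation was used here, so peaks were not assigned to genes.

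The read recovery, the ratios, the list percentiles and the additive fit were tested on simulated data. All of 2872 simulated rows were recovered as the reads they were made from, up to any common factor of a row's reads. The loss of such a factor was thus not tested. With 200 genes changed in both knockdown libraries and counting noise only, over 10522 genes, 100% of genes changed 3-fold and 100% of those changed 6-fold passed the 2-fold limit in each knockdown comparison. Among unchanged genes, 2 passed without hemin and 0 with hemin. The additive knockdown fit called 100% of the changed genes at both sizes and 8 unchanged ones. The alternatives were equal medians, plain totals, no floor, a floor of 20 and a pseudocount of 0.1. Plain totals divided each library by the sum of its reads over transcript length, not by its read total, and used no TMM factor. Added after the data were seen were the deposited values as they stand and the transcript with the most reads. So were the removal of a trend with transcript length and an ordinary model without pooling.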

Results

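The study profiled RNA in HEL cells, a human erythroleukaemia line that can be pushed towards red cell features by hemin, and mapped KAP1 on chromatin of mouse erythroblasts. KAP1, encoded by TRIM28, is a corepressor recruited by KRAB zinc finger proteins. By its title, the series concerns KAP1, microRNAs and the control of mitophagy in red cell formation. The 4 HEL groups crossed KAP1 knockdown with hemin, with 1 library each. The control columns are those headed Ctrl, taken as the HEL samples labelled KAP1 WT because that is the one other genotype; the names themselves differ. No difference below has a replicate check. Genes without reads in 1 of the libraries may be absent from the table and so from every count below. Depth was between 23294701 and 40777133 reads on the chosen transcripts per library.

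TRIM28 (NM_005762) was lower in both knockdown libraries. Its level was 315 scaled TPM in the knockdown and 428 in the control without hemin, a log2 ratio of -0.44 or 1.36-fold. With hemin it was 189 against 398, a log2 ratio of -1.07 or 2.10-fold. The size of the knockdown depends on scaling: the deposited values as they stand gave -0.99 without hemin and -0.86 with hemin. TRIM28 is also among the 5 rows deposited as whole numbers, whose origin and reads are not known, so its ratios have no counting interval and it is a weak check of the labels and of the knockdown.

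The first comparison asked what KAP1 knockdown does in cells that were not activated. The eosinophil granule protein gene PRG2 (NM_002728) was at 6.79 scaled TPM against 1366 in the control, and ITGB2 (NM_000211), a leukocyte integrin chain, at 7.97 against 128. THBS1 (NM_003246), which encodes a platelet granule protein, was at 72.3 against 4.34. Of 10871 genes at the floor, 674 were at least 2-fold higher and 746 at least 2-fold lower. With plain library totals, which are sums of reads over transcript length, this split was 957 higher and 518 lower. It was 806 and 638 with equal medians, and 717 and 686 with the transcript with the most reads. The balance of directions thus depends on the scaling and on the transcript chosen. Plain totals moved the median of all genes by 0.14 here and by 0.10 with hemin, and the deposited values as they stand gave 145 and 2442.

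With hemin, THBS1 was at 208 scaled TPM in the knockdown against 4.81 in the control, PRG2 at 10.5 against 644 and ITGB2 at 1.80 against 64.1. Of 10882 genes, 652 were at least 2-fold higher and 450 at least 2-fold lower. The split was 821 and 362 with plain library totals, and 1105 and 297 with the deposited values as they stand.

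The 2 activation states share no library, and many genes differed the same way in both. At least 2-fold higher in both were 280 of 10605 genes, where independent lists would share 36.4, and 226 were lower in both, where 26.6 would be shared. Both states set knockdown cells against control cells, so any other difference between these cells could recur in both. The excess over independent lists therefore does not single out KAP1. Across genes, which are not independent replicates, the 2 log2 ratios had a Pearson r of 0.69 and a Spearman rho of 0.62. With plain library totals 409 were higher and 176 lower, and with the deposited values as they stand 116 and 224. The 12 genes furthest up were THBS1, ACTL8, KBTBD12, NOV, OR2T8, RD3, EPHB1, NRGN, OR2T33, TXNIP, GRIP1 and MYL9. NRGN, a calmodulin-binding protein gene, had log2 ratios of 2.53 and 2.64 without and with hemin, and TXNIP, which encodes a thioredoxin-binding protein, 2.39 and 2.73. The olfactory receptor genes OR2T8 (3.10 and 3.16) and OR2T33 (2.50 and 2.76) are close relatives that may share reads. The 12 genes furthest down were PRG2, ITGB2, TPSAB1, TPSB2, HSPA6, CHAC1, FAM83A, APOE, C11orf9, HSPA7, FGFR3 and DDIT4. PRG2 had log2 ratios of -7.55 and -5.87. The mast cell tryptase genes TPSAB1 (-4.08 and -3.53) and TPSB2 (-4.31 and -3.52) are near-identical, as are the heat shock gene HSPA6 (-3.52 and -3.75) and its relative HSPA7 (-2.95 and -3.39), so the authors' counting could have split their reads. APOE, an apolipoprotein gene, had -3.31 and -3.86, and the growth factor receptor gene FGFR3 -2.93 and -3.40.

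**Figure D1:**
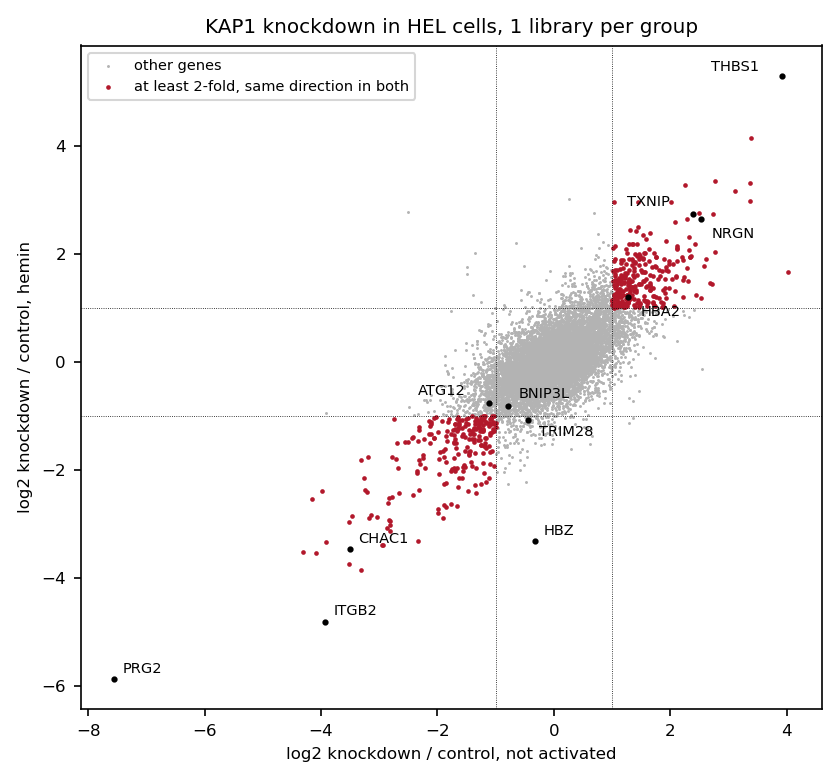
Log2 ratio of knockdown over control per gene without hemin (horizontal axis) and with hemin (vertical axis), 1 library per group; coloured points are the genes at least 2-fold apart in the same direction in both. The 280 genes higher in both lie at the upper right and the 226 lower in both at the lower left, with THBS1 and PRG2 at the far ends.

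In the additive fit over 11148 genes, 1295 rose and 1147 fell with the knockdown by limma with Benjamini-Hochberg adjustment. TRIM28 fell by 0.76 on the log2 scale (SE 0.22, limma adjusted p = 0.0049). These calls rest on a spread pooled across genes: an ordinary model without pooling called 0 genes, with 1094 at an unadjusted p under 0.05. The counts of list members that rose or fell below carry the same limit.

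Genes of cell division were higher after knockdown. The cell cycle list had a median log2 ratio of 0.97 without hemin and 1.34 with hemin, both above all of the 10000 random lists. Of its 29 members 25 rose, 0 fell and 4 did not pass in the additive fit, and 26 rose when adjusted over the list alone. The mitotic kinase PLK1 had 1.65 and cyclin CCNB1 1.61 without hemin, and the proliferation marker MKI67 had 1.57 without and 2.02 with hemin. Histone genes had medians of 1.70 and 0.95, with 26 of 30 members rising and 26 adjusted over the list alone. HIST1H3H had 2.68 without hemin and HIST1H2BC 2.96 with it. Structural RNAs without a poly-A tail, such as RMRP and RN7SK, had a median of 2.50 in the same comparison with hemin and -0.65 without. Between the knockdown libraries, with hemin over without, these RNAs had a median of 3.27 and histone genes one of 0.13.

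The list of unfolded protein and amino acid stress genes had medians of -1.36 and -1.24, with 16 of 21 members falling, 1 rising and 4 not passing, and 16 falling and 1 rising when adjusted over the list alone. CHAC1, a glutathione-degrading enzyme gene, had -3.51 and -3.47, ASNS, asparagine synthetase, -3.31 and -1.82, and DDIT4, a stress-induced inhibitor of mTOR, -3.18 and -2.89. Ribosomal protein genes had medians of -0.79 and -0.73. In that list 65 of 84 fell, 0 rose and 19 did not pass, and 70 fell when adjusted over the list alone. RPS27 had -1.86 without hemin and RPS20 -1.45 with it.

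Lineage lists went different ways. Myeloid and monocyte markers had medians of -0.93 and -0.77, and 5 of 9 members fell (6 adjusted over the list alone), among them the macrophage marker CD68 with -1.48 and -2.39. Megakaryocyte markers had a median of 0.06 without hemin, within the random range of -0.32 to 0.33, and 0.68 with hemin, above all random lists. At least 1.5-fold apart were 6 members higher and 7 lower without hemin, and 11 higher and 1 lower with it. The additive fit takes both states together, so its count does not show this difference. CD9 was lower in both states, at -1.71 and -1.50. Of 22 members 9 rose and 1 fell (10 and 1 adjusted over the list alone), with THBS1 at 3.91 and 5.30 and CLEC1B, a platelet receptor gene, at 2.72 without hemin. Stem and progenitor markers had medians of -0.05 and -0.05, within the random ranges, with the receptor gene KIT at -1.25 and -2.27 and MYCN at 2.10 and 1.59. Of 8 members 1 rose and 2 fell (2 and 3 adjusted over the list alone). Interferon response genes had medians of -0.39 and -0.33. Of 29 members 7 fell and 1 rose (9 and 2 adjusted over the list alone), with XAF1 at -2.43 and -1.41 and BST2 at -1.54 and -1.91. With a floor of 20 the median with hemin was -0.26, inside its random range.

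The lists of red cell genes had medians inside the random ranges after knockdown, except haem synthesis with hemin. The erythroid membrane list had medians of 0.04 and 0.01, within the random ranges, with 5 of 27 members rising and 4 falling (6 and 6 adjusted over the list alone). RHCE, a blood group gene that shares sequence with RHD, had 1.97 and 1.36, and the erythropoietin receptor gene EPOR -1.27 and -1.46. Erythroid transcription factors had medians of 0.07 and -0.32, within the random ranges, and of 12 members 1 rose and 1 fell (1 and 0 adjusted over the list alone). The GATA1 cofactor gene ZFPM1 had 1.55 and 1.21. Haem synthesis and iron genes had medians of -0.03 and -0.42, the second below the random range of -0.26 to 0.31. Of 17 members 1 rose and 6 fell (1 and 7 adjusted over the list alone), with ALAS1, the first enzyme of haem synthesis, at -1.59 without hemin and UROD at 0.88 and 1.20. Globins had medians of 0.17 and 0.20, within the random ranges, and of 9 members 2 rose and 1 fell (2 and 1 adjusted over the list alone). The near-identical alpha globin genes HBA1 (1.29 and 1.18) and HBA2 (1.27 and 1.19) were higher, while the fetal gamma globin genes HBG1 (0.05 and 0.20) and HBG2 (0.02 and 0.18) were close to their control. Other globins differed between the states: HBB had -1.33 and 0.38, HBZ -0.33 and -3.32, and HBE1 0.70 and -0.44.

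The series title names mitophagy. The autophagosome list had medians of -0.33 and -0.22 after knockdown, just below the random ranges of -0.27 to 0.25 and -0.21 to 0.21. This position did not hold under other settings: without hemin the value was -0.13 with a floor of 20, -0.18 with the length trend removed and -0.15 as a mean, each inside its random range, and with hemin it was -0.22, -0.19 and -0.14, again inside. Of 29 members 2 rose, 4 fell and 23 did not pass (2 and 4 adjusted over the list alone). ATG12, a ubiquitin-like conjugation factor, had -1.12 and -0.77, ATG4D had 1.44 and 0.95, and the LC3 gene MAP1LC3B -0.97 and -0.23. BECN1 had -0.15 and -0.21. Mitophagy receptors and regulators had medians of -0.12 and -0.24, within the random ranges, with 3 of 19 members rising and 3 falling (3 and 3 adjusted over the list alone). BNIP3L, the receptor for mitochondrial clearance in maturing red cells, had -0.79 and -0.82, CALCOCO2 -1.17 and -1.12, and BNIP3 1.07 and 0.31. BNIP3L, ATG12 and BECN1 were among the rows deposited as whole numbers, so these ratios have no counting interval and hold only if those rows carry depth as the others do.

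**Figure D2:**
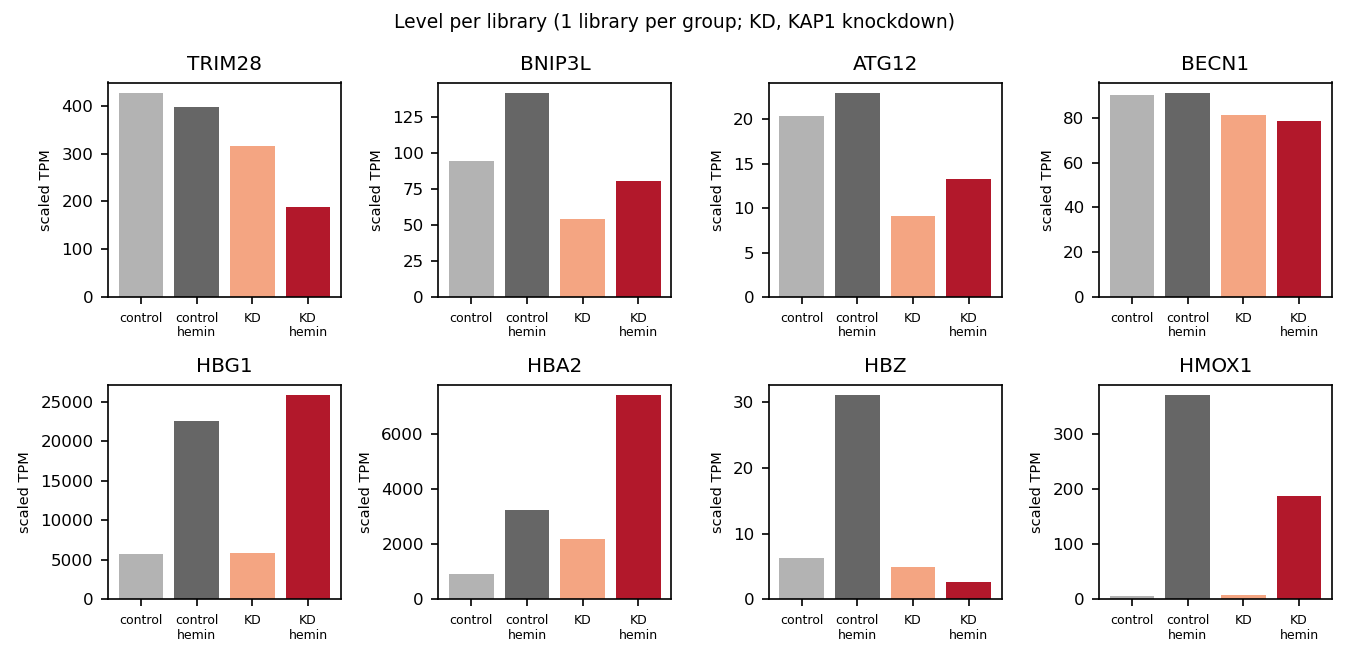
Level in scaled TPM (vertical axis, linear from 0) of 8 genes in the 4 HEL libraries, 1 bar per library. TRIM28 stands at 428 and 398 in the controls and 315 and 189 in the knockdown, and BNIP3L at 94.1 and 142 against 54.3 and 80.3; TRIM28, BNIP3L, ATG12 and BECN1 come from rows of whole numbers.

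Zinc finger genes had medians of -0.33 and -0.15, below the random ranges, with 32 of 342 falling and 5 rising (23 and 4 adjusted over the list alone), ZNF385D at 2.12 and 2.10 and ZNF853 at -2.00 without hemin. In the same fit 1147 of all 11148 genes fell and 1295 rose. The share of zinc finger genes that fell was thus no larger than among all genes, and the share that rose was smaller. Cholesterol synthesis genes had 0.24, within the random range, and 0.47, above it, with 7 of 21 rising and 0 falling (8 and 0 adjusted over the list alone), HMGCS1 at 1.41 with hemin. Haem and oxidative stress genes had -0.18, within the random range, and -0.67, below it. Of 22 members 6 fell and 1 rose (8 and 1 adjusted over the list alone), with SLC7A11 at -2.42 and -1.39 and NQO1 at 1.86 and 1.68. Respiratory chain genes had 0.16 and 0.24, the second just above its random range of -0.15 to 0.23, with 6 of 42 rising and 2 falling (5 and 2 adjusted over the list alone), SDHA at 0.89 and COX4I1 at -0.81 without hemin. The value with hemin lay inside the random range with a floor of 20 (0.24), with the length trend removed (0.10) and as a mean (0.20). p53 targets had -0.12 and 0.13, within the random ranges, with 2 of 21 rising and 6 falling (5 and 7 adjusted over the list alone), BBC3 at -1.71 and -2.02. Members of the KAP1 repressor complex had 0.04 and 0.13, within the random ranges, with 3 of 27 rising and 0 falling (3 and 0 adjusted over the list alone), UHRF1 at 1.42 and 1.61. Imprinted genes had 0.05 and -0.07, within the random ranges, with 3 of 17 rising and 1 falling (3 and 1 adjusted over the list alone), SGCE at 1.93 with hemin. Only 4 microRNA host or precursor genes reached the floor, too few for a median; 2 fell and 0 rose (2 and 0 adjusted over the list alone), with MIR17HG at -1.87 and -0.07 and MIR22HG at -1.67 and -1.60. None of 12 clustered protocadherin genes reached the floor, and 0 genes of the mitochondrial genome were in the table.

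**Figure D3:**
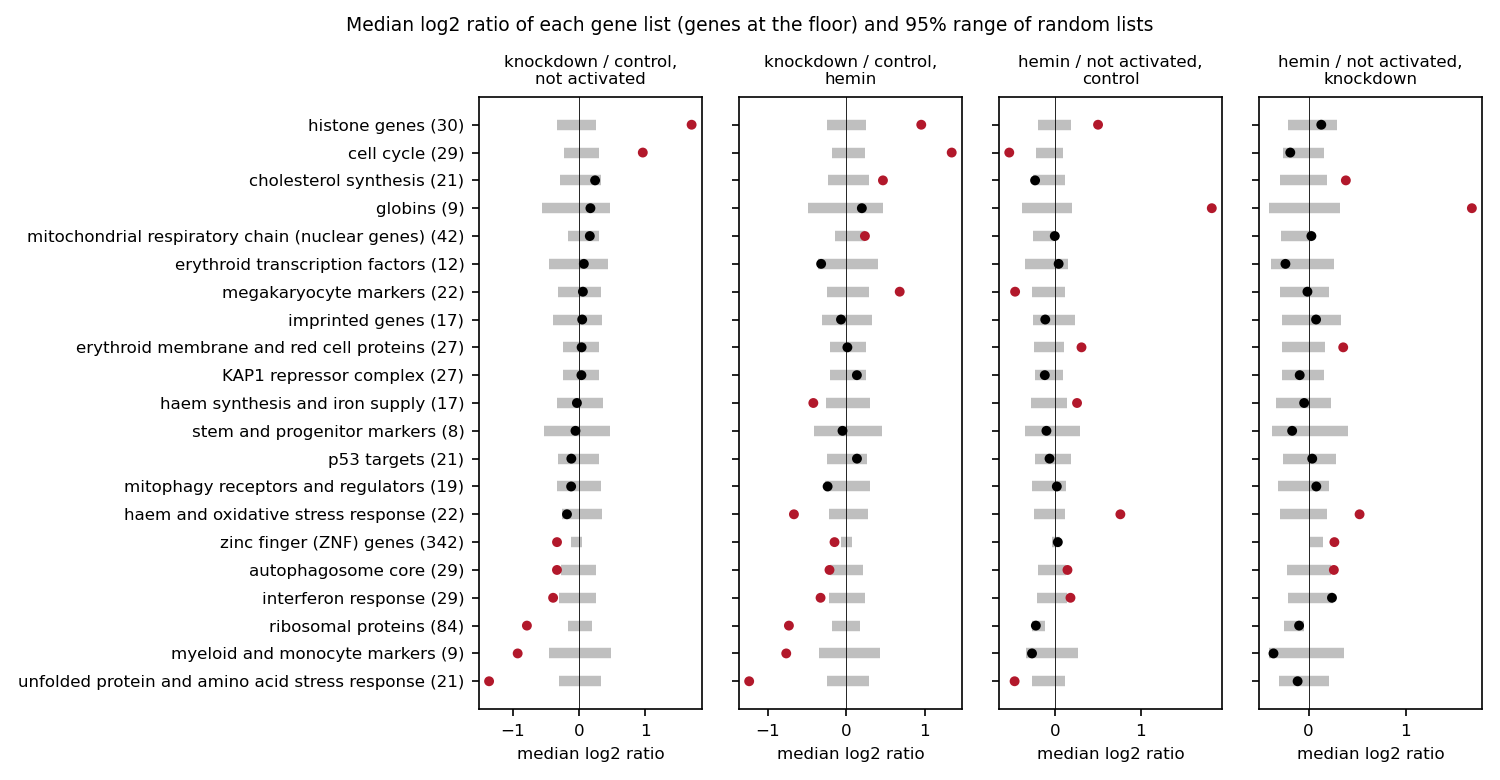
Median log2 ratio (horizontal axes) of the 21 lists with at least 5 genes at the floor, in the 4 comparisons; grey bars span 95% of random lists matched on expression, and coloured points lie outside them. Without hemin 8 lists lay outside after knockdown and with hemin 13, against 10 for hemin in the control and 6 for hemin in the knockdown.

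Hemin activation was compared next, first in control cells. HMOX1 (NM_002133), haem oxygenase 1, was at 369 scaled TPM against 5.59, a 60.8-fold ratio, the gamma globin gene HBG2 at 28603 against 7090, and UNC5B, a netrin receptor gene, at 3.92 against 50.5. Of 10800 genes 258 were at least 2-fold higher and 296 lower. Plain library totals turned this balance to 290 and 265, and the deposited values as they stand gave 453 and 195.

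In knockdown cells HMOX1 was at 186 scaled TPM with hemin against 8.60 without, HBG2 at 32509 against 7181 and UNC5B at 1.65 against 30.4. Of 10807 genes 244 were at least 2-fold higher and 184 lower. Equal medians turned this balance to 179 higher and 263 lower, and the deposited values as they stand gave 5030 and 11, since the library with hemin was the deepest and the other the shallowest.

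Genes that differed with hemin the same way in control and knockdown numbered 56 higher and 60 lower of 10459, where independent lists would share 4.67 and 3.53. The Pearson r across genes was 0.43 and the Spearman rho 0.39. Equal medians gave 43 higher and 72 lower, plain library totals 60 and 59, and the deposited values as they stand 328 and 5. The 12 furthest up were HMOX1, SLC38A6, MLLT11, SLCO2B1, HBG2, HBG1, HBA2, HBE1, HBA1, JUN, ARRDC3 and RBM11. HMOX1 had log2 ratios of 5.93 in the control and 4.36 in the knockdown, MLLT11 2.84 and 2.17, the embryonic globin gene HBE1 2.86 and 1.73, and the transcription factor gene JUN 1.56 and 1.88. The 12 furthest down were UNC5B, KIAA0125, COL6A1, EPHA1, EXOC3L2, CAPN5, S100P, CCND1, CXCR4, MATK, UBL4B and NKD1. UNC5B had -3.53 and -3.85, the cyclin D1 gene CCND1 -1.67 and -1.81, and the chemokine receptor gene CXCR4 -1.79 and -1.66.

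In the additive fit 305 genes rose and 342 fell with hemin by limma with Benjamini-Hochberg adjustment. The ordinary model without pooling called 0, with 796 at an unadjusted p under 0.05.

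Globins had a median log2 ratio of 1.83 with hemin in the control and 1.68 in the knockdown, above all random lists, and 6 of 9 rose and 0 fell (7 and 0 adjusted over the list alone). Haem and oxidative stress genes had 0.76 and 0.52, and 10 of 22 rose and 0 fell (13 and 0 adjusted over the list alone), with GCLM, a glutathione synthesis gene, at 1.36 and FTL, ferritin light chain, at 1.19 in the knockdown. Erythroid membrane genes had 0.31 and 0.36, with 5 of 27 rising and 0 falling (7 and 0 adjusted over the list alone), EPB42, a red cell skeleton protein gene, at 1.91 and 1.15. The cell cycle list had -0.53 in the control, below all random lists, and -0.19 in the knockdown, within its random range, with 3 of 29 falling (9 adjusted over the list alone). Megakaryocyte markers had -0.46 in the control and -0.01 in the knockdown, with PF4, a platelet chemokine gene, at -2.00 and 0.85. Autophagosome genes had 0.14 and 0.26, just above the random ranges, with GABARAPL1 at 2.27 and 1.10; in the knockdown the value was 0.19 with a floor of 20 and 0.14 with the length trend removed, inside them. Of 29 members 1 rose (1 adjusted over the list alone). Haem synthesis and iron genes had 0.26 in the control, above the random range, or 0.13 as a mean, inside it, and -0.05 in the knockdown. In that list ALAS1 had -1.80 and -0.86 and the transferrin receptor gene TFRC -1.37 and -0.71. Histone genes had 0.50 in the control, above all random lists, and 0.13 in the knockdown, inside its range, where RNAs without a poly-A tail had medians of 1.08 and 3.27. The unfolded protein and amino acid stress list had -0.47 and -0.11, the first below its range. Interferon response genes had 0.18 in the control, above the random range, or 0.07 with a floor of 20, inside it, and 0.24 in the knockdown, inside its range. In the knockdown, zinc finger genes had 0.26 and cholesterol synthesis genes 0.38, above the random ranges. The mitophagy list had 0.02 and 0.08, within the random ranges, with BNIP3L at 0.59 and 0.56.

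The knockdown effect differed by at least 2-fold between the activation states for 411 genes in the direction of hemin and 287 the other way, of 11148 at the floor over 4 libraries. No test of this difference was possible beyond the additive fit's own residual. Equal medians gave 309 and 393, and the deposited values as they stand 3769 and 29. The 5 highest differences were RNU2-2, RN5-8S1, GNLY, SNORD3C and PPBP. Structural RNAs lead this group: the 5.8S ribosomal RNA gene RN5-8S1 was at 3459 scaled TPM in the knockdown with hemin and 80.4, 460 and 509 in the other libraries. The 5 lowest were SHISA3, HBZ, HOXD1, DES and PIR. The embryonic zeta globin gene HBZ was at 31.1 in the control with hemin and 2.65 in the knockdown with hemin, against 6.27 and 4.89 without.

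KAP1 chromatin binding in sorted mouse CD71 and Ter119 positive erythroblasts was given as 45024 peaks on 21 chromosomes. Their median width was 645 bp, with quartiles of 538 and 805 bp, and they covered 31.8 Mb. The authors' score ran from 50 to 1559 with a median of 63.2, and 8.02% of peaks had a score of at least 100. The highest score lay on chromosome 17 (mm9) from 4625909 to 4626756, followed by a peak of 6168 bp on chromosome 17 from 39979777 to 39985944 with a score of 1279 and a peak on chromosome 11 from 24999938 to 25000368 with 705. The fourth, on chromosome 5 from 114622632 to 114623481, scored 523, and the other 6 of the top 10 lay on chromosomes 1, 9, 14 and 2 with scores of 357 to 459. Chromosome 11 had the most peaks per Mb up to its last peak, 24.5, and chromosome 3 the fewest of the autosomes, 14.5. Chromosome X had 1.39, and chromosome Y, with 13 peaks and a last peak at 2.57 Mb, had 5.06. Taking 1 Mb windows, the densest was on chromosome 15 from 80000001 to 81000000 with 55 peaks, against a median of 16 over windows with a peak. Peaks at gene groups were not analysed here, since no mouse annotation was used.

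**Figure D4:**
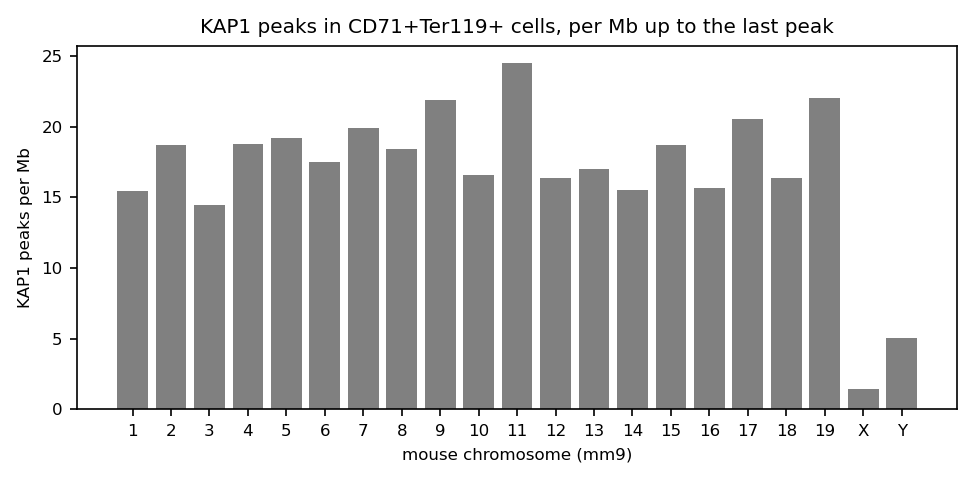
KAP1 peaks per Mb (vertical axis) on each mouse chromosome (mm9), counted up to the end of the last peak. Autosomes lie between 14.5 and 24.5, chromosome X at 1.39 and chromosome Y, whose last peak ends at 2.57 Mb, at 5.06.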

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

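The tests of RNA without a poly-A tail and of the read total were chosen after the results were seen. Genes at least 2-fold apart one way in 1 activation state and the other way in the other were looked at again; the difference was not tested for any of them, since each group is 1 library. For the knockdown, the log2 ratio with hemin minus that without was 2.63 for BCYRN1, 2.36 for CCR4, -2.43 for PIR, 3.38 for PPBP, 3.25 for RMRP, 5.27 for RN5-8S1, -2.41 for RPL13AP6 and 3.12 for SNORA73B. For hemin, the ratio in the knockdown minus that in the control was 2.70 for MPZL3, and again 3.38 for PPBP and 3.12 for SNORA73B, the same difference of 4 libraries.

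Histone genes were higher in both knockdown libraries, with medians of 1.70 without hemin and 0.95 with it. A trend with transcript length was argued against as the whole cause: with it removed the medians were 1.49 and 0.76, still above the random ranges. RNA without a poly-A tail had a median of -0.65 in the knockdown without hemin. Its members went both ways, from -2.15 for RNU2-2, with 1 read in that library, to 1.45 for RPPH1. Such RNA thus gave no sign of a general carry-over there, but members this few and low cannot exclude it. With hemin the tables conflict: its median was 2.50 over the control, but between the knockdown libraries it was 3.27 higher with hemin while histone genes were at 0.13, inside their random range, which goes against carry-over unless hemin otherwise lowered histone RNA. Carry-over with hemin stays open and without hemin is not excluded, and a higher share of dividing cells after knockdown was not tested.

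As deposited, BECN1, BNIP3L and ATG12 were all lower in the knockdown without hemin, the library with the fewest reads. After scaling, BECN1 had a log2 ratio of -0.15, inside the interquartile range of all genes from -0.42 to 0.40, so the lower read total may account for its deposited difference. The higher of the BNIP3L and ATG12 ratios was -0.79, below that range. The spread of these ratios is not known, so without hemin the part of the read total stays open for them. With hemin the knockdown library had more reads than the control. Deposited values there were still lower, 1245 against 1893 for BNIP3L and 206 against 307 for ATG12, while BECN1 was at 1222 against 1219. A low read total cannot account for the differences of BNIP3L and ATG12 with hemin. All 3 rows hold whole numbers, and if they were made in another way than the rest these scaled ratios are wrong by an unknown amount; that was not testable for these genes.

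Zinc finger genes had a median of -0.33 in the knockdown without hemin, where longer transcripts had lower log2 ratios across genes (Spearman rho -0.22). With that trend removed the median was -0.26, below the random range of -0.10 to 0.06, which argues against length as the whole cause. An effect of KAP1, which binds KRAB zinc finger proteins, was not tested against other causes and stays open.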

How the results depend on the processing

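The deposited values as they stand, the removal of a length trend, the transcript with the most reads, the ordinary model and the reading of whole numbers as counts were chosen after seeing the data. All counts of genes in the ratios stayed within 1.5 times with equal medians, plain totals and a pseudocount of 0.1. So they did with the transcript with the most reads and with removal of the length trend. Of 84 list values, 84 kept their side of the random range with plain totals. That scaling shifts a list and its random lists almost alike, so this outcome was nearly fixed in advance and is no check of the lists. With a floor of 20, 77 kept their side, with the length trend removed 75 and with means 78. The autophagosome list after knockdown was inside the range under the last 3 of these. Lists that came to lie outside it were, with a floor of 20, imprinted genes after knockdown without hemin (0.57); with the length trend removed, cholesterol synthesis in that comparison (0.30), the respiratory chain with hemin in control (0.04) and knockdown (0.05), and myeloid markers (-0.41) and interferon genes (0.31) with hemin in the knockdown; and as means, p53 targets after knockdown without hemin (-0.37) and interferon genes with hemin in the knockdown (0.35). The cause was not tested. Plain totals shift the median of all genes by 0.14 and 0.10 in the knockdown comparisons. Of the 506 genes at least 2-fold apart in both states, 456 were shared with plain totals, 444 with the length trend removed and 266 with the deposited values. The deposited values shift the median of all genes by -0.53, 0.22, 0.19 and 0.94 in the 4 comparisons. Higher and lower counts with them were 145 and 2442 for knockdown without hemin, 1105 and 297 with hemin, 453 and 195 for hemin in the control, 5030 and 11 in the knockdown, 328 and 5 for hemin in both, and 3769 and 29 for the difference; 116 were higher in both after knockdown. Uncorrected depth, by construction, moves them. A floor of 20 tests fewer genes and gave 442 and 484, 404 and 277, 173 and 135 for knockdown without hemin, with hemin and in both, 157 and 183, 113 and 84, 28 and 30 for hemin in the control, the knockdown and both, and 223 and 153 for the difference. No floor tests more and gave 383 and 297 for hemin in the knockdown and 623 and 504 for the difference. TRIM28 without hemin was -0.37 with equal medians, -0.30 with plain totals, -0.99 as deposited and -0.58 with whole numbers read as counts; with hemin it was -1.09, -0.97, -0.86 and -1.06, by the construction of each scaling. The additive fit called 0 and 0 genes for knockdown and 0 and 0 for hemin without pooling, since 1 residual degree of freedom leaves little power. Peaks at or above the median score numbered 22543 and those at the top of the scores 4504, by construction. The planned count models, peaks at gene groups at other distances and their score limits were not run. No paired analysis of replicates was possible because each group was 1 library. The additive fit compares within each activation state. Depth limits genes with few reads: 1092 genes had under 10 reads in the knockdown without hemin.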

Other observations

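The test on chromosome X was chosen after its peak number was seen. In the chromosome order of the 9355 tested genes that were placed, genes higher in both knockdown libraries were neighbours more often than random sets. No limit was set on distance, and genes that were not tested could lie between the members of a pair. Of the 280 genes, 237 were placed by the gene order of GRCh38.p14, and 13 adjacent pairs were found, against a median of 6 and an upper end of 11 for the central 95% of 10000 random sets; the highest random set had 17. The pairs include the alpha globin genes HBA2 and HBA1, OR2T8 and OR2T33, and TUBA4A and TUBA4B, which are relatives that may share reads, and also IGFBP2 and IGFBP5, CLU and SCARA3, and KHK and CGREF1. Without those 3 pairs 10 are left, which is inside the random range, although the random sets kept their own relatives. Shared regulation of neighbours may contribute, but shared reads were not separated from it.

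Chromosome X held 231 KAP1 peaks, 7.66% of the autosomal number per Mb. A hypothesis is lower depth on a single X chromosome: if scores there were 0.5 times those of autosomes, 8.04% of autosomal peaks would keep the lowest score of 50. The 2 percentages are close, although the scaling of scores with depth is assumed. Chromosome Y would also be single. Its 13 peaks came to 5.06 per Mb, but only up to a last peak at 2.57 Mb, against 1.39 on X up to 166 Mb. The median scores were 67.1 on Y and 62.0 on X. So few peaks on so short a stretch give no firm comparison with X. The hypothesis therefore stays open, and the removal of repeats by the authors was not tested.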
